A study of Mus musculus with 14 samples.

How the data were processed

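RNA was extracted with the RNeasy Mini Kit and libraries were made from 1.0 ug of total RNA with the TruSeq Stranded mRNA kit, per the labels. Per the submitters' processing notes, reads were processed with Trim Galore, STAR, RSEM and DESeq2, with no versions or parameters given. The genome build, the annotation and the strand used for counting were not stated. The expected count values were deposited by the authors as RSEM estimates per gene, with 1 column per library and no normalization. Between 3.30% and 6.11% of the values in a library were fractional. The TPM values were deposited by the authors as RSEM output. The log2 fold changes came from the authors' DESeq2 comparison, per the file headers, which do not state any shrinkage. The p-value and adjusted p columns came from the same DESeq2 comparison, per the file headers.

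The tables held 56941 gene IDs, of which 56131 had a symbol. Groups came from the genotype words of the table columns and the stage of each table, and the sample titles gave the same group sizes. In 11 of 14 samples the library name in the description belonged to a sample whose title gave another group. All 14 library names were found among the table columns. The columns called dfl were read as the ff libraries. Replicate numbers in this text follow the order of the table columns within each group. They are not the numbers in the sample titles. Sex was read from chromosome Y genes and Xist.

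Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr, libraries scaled by TMM, and genes tested with edgeR's robust quasi-likelihood F test, each stage in its own fit. Values of p were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. CPM are TMM-scaled counts per 1000000 counts, with SD between libraries, and log CPM used a prior count of 2. The interaction and the stage difference in ff came from 1 fit of the 4 groups. Tests were two-sided unless said otherwise.

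The comparisons, the 34 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists held 822 distinct symbols, 815 of them in the tables, with 786 tested at E12.5 and 779 at E18.5. Lists with at least 4 tested genes were tested with camera of limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Member counts are given over all genes tested and adjusted over the list alone. Genes named were Sbno1, Trp53 and Emx1 and, at each stage, up to 8 raised and 8 lowered most by log2 fold change among calls with a mean of at least 1 CPM in the higher group and non-overlapping groups, leaving out predicted genes and pseudogenes. From each list up to 4 members with the lowest p were taken, and from the interaction 5 genes per direction with the lowest p. Hopx, Olig2 in the ventral list, Npy, members given as exceptions and genes said to be picked later stand outside that rule. Exon overlaps of named genes were looked up in GENCODE M21.

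Alternatives were DESeq2 size factors, upper quartile scaling, the DESeq2 Wald test, limma-voom, no filter, a mean of at least 1 CPM, 1 fit of all 14 libraries, sex as a covariate, removal of erythroid, chromosome Y, Xist and mitochondrial genes, a fold change of at least 1.5, log2(TPM + 1) with an exact permutation test, and each library left out in turn. Alternatives added after the data were seen were a correction for length and GC content by splines with 5 degrees of freedom each on the longest GENCODE M21 transcript, male libraries alone, counts thinned to the shallowest library of the stage, E18.5 dcKO reduced to replicates 2 and 4, both shallow libraries left out, and the alternatives for the stage difference in ff. Blocking on the first number of the library names was not run, because in the column names it does not cross genotype. Groups from the column names were those used, so they were not an alternative.

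Simulated changes in counts with the spread of these libraries were put through the same steps. At E12.5, 44% of 100 genes changed 1.5-fold and 76% of 100 changed 2-fold were recovered, with 16 false calls among 17853 genes. At E18.5 the shares were 69% and 91% with 11 false calls, and for the interaction 42% and 62% with 5. As a share of all calls made, the false calls at E12.5 were above the adjusted p threshold. At E18.5 they were slightly above it, and for the interaction below it. The E12.5 calls may therefore hold more false ones than the threshold implies. In each comparison both changed lists and none of 20 unchanged lists were called. The genes were drawn independently, so this does not cover lists whose genes move together, as synapse genes did at E12.5 (estimated correlation 0.73). The length and GC correction took the calls among unchanged genes under a simulated length trend from 2286 to 13 at E12.5 and from 4550 to 12 at E18.5. At E12.5 it also lowered the share of changed genes called, from 52% to 43% at 1.5-fold and 83% to 72% at 2-fold. At E18.5 these were 76% and 77%, and 92% in both fits. The simulated trend was the same in all dcKO libraries, which the real one was not, and at E18.5 its sign was opposite (Spearman -0.79 against 0.14). Sequence reads, transcript-level values and exon-level coverage were not analysed here.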

Results

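Polyadenylated RNA of mouse embryonic forebrain was sequenced in 14 libraries, of which 6 came from E12.5 telencephalon and 8 from E18.5 cerebral cortex (E, day of gestation). Libraries with the floxed alleles alone (ff) were set against double conditional knockout libraries (dcKO), in which floxed Sbno1 and Trp53 were combined with the Emx1-Cre driver. No group carried the driver without floxed alleles or a single knockout. Effects of the driver and of either deletion therefore cannot be told apart, at the driver locus Emx1 included. Sbno1 is a mouse homologue of the fly gene strawberry notch, Trp53 encodes the transcription factor p53, and Emx1 is a homeobox gene of dorsal telencephalic progenitors. E12.5 had 3 ff and 3 dcKO libraries, and E18.5 had 4 of each. Total expected counts at E12.5 were 4.92 M in ff replicate 1 and 42.0 to 67.4 M in the other 5 libraries. At E18.5 they were 5.98 M in replicate 1, by column order, of the libraries labelled dcKO and 48.6 to 82 M in the other 7. Chromosome Y and Xist counts marked every dcKO library as male at both stages. Of the ff libraries 1 of 3 at E12.5 and 2 of 4 at E18.5 were female, so sex was unevenly spread over the groups. The choroid plexus transcript Ttr was at 1.82 TPM in E18.5 dcKO replicate 3 and at 1401 to 3203 TPM in the other 7 E18.5 libraries.

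The labels were first checked on the targeted genes and the driver locus. Emx1 (ENSMUSG00000033726.9) was lower in dcKO at both stages, without overlap between the groups. At E12.5 it was 62.3 ± 4.42 CPM in ff and 31.9 ± 1.47 CPM in dcKO (SD, n = 3 each; log2 fold change -0.96, SE 0.08, adjusted p = 0.0083 in edgeR). That call was lost without dcKO replicate 2 (adjusted p = 0.11) or 3 (0.063) and with sex as a covariate (0.051) in edgeR. At E18.5 it was 26.4 ± 1.26 CPM in ff and 15.1 ± 0.88 CPM in the libraries labelled dcKO (SD, n = 4 each; log2 fold change -0.81, SE 0.07, adjusted p = 8.3e-06 in edgeR). Sbno1 (ENSMUSG00000038095.16) at E12.5 was 106 ± 9.29 CPM in ff and 70.2 ± 5.77 CPM in dcKO (SD, n = 3 each), lower in all 3 dcKO libraries. Its log2 fold change of -0.59 (SE 0.09) missed the threshold (adjusted p = 0.051 in edgeR). After a correction for transcript length and GC content it was -0.33, past the threshold (adjusted p = 0.044 in edgeR), as it also was without dcKO replicate 1 (-0.65, adjusted p = 0.015). At E18.5 its counts did not differ detectably: 73.6 ± 1.31 CPM in ff and 72.4 ± 4.24 CPM in the libraries labelled dcKO (SD, n = 4 each; log2 fold change -0.03, SE 0.05, adjusted p = 0.68 in edgeR). Its deposited TPM went the other way at E18.5, with a log2 difference of 0.34 (exact permutation p = 0.0286, the smallest possible). Trp53 (ENSMUSG00000059552.14) at E12.5 was 123 ± 15.4 CPM in ff and 106 ± 2.32 CPM in dcKO (SD, n = 3 each; log2 fold change -0.23, SE 0.09, adjusted p = 0.22 in edgeR). At E18.5 Trp53 was 75.0 ± 2.53 CPM in ff and 65.0 ± 6.25 CPM in the libraries labelled dcKO (SD, n = 4 each). Its log2 fold change was -0.20 (SE 0.06, adjusted p = 0.032 in edgeR), past the threshold in 3 of 8 fits with 1 library left out. It missed it without ff replicate 3 (adjusted p = 0.056) or 4 (0.054) and without replicate 1 (0.063), 3 (0.090) or 4 (0.055) labelled dcKO, in edgeR. The labels do not give the floxed exons, and whole-gene counts include reads from exons that remain. These values therefore cannot show how much of either gene was deleted. Because Sbno1 counts were not lower at E18.5, directions at that stage are given for the libraries labelled dcKO.

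**Figure D1:**
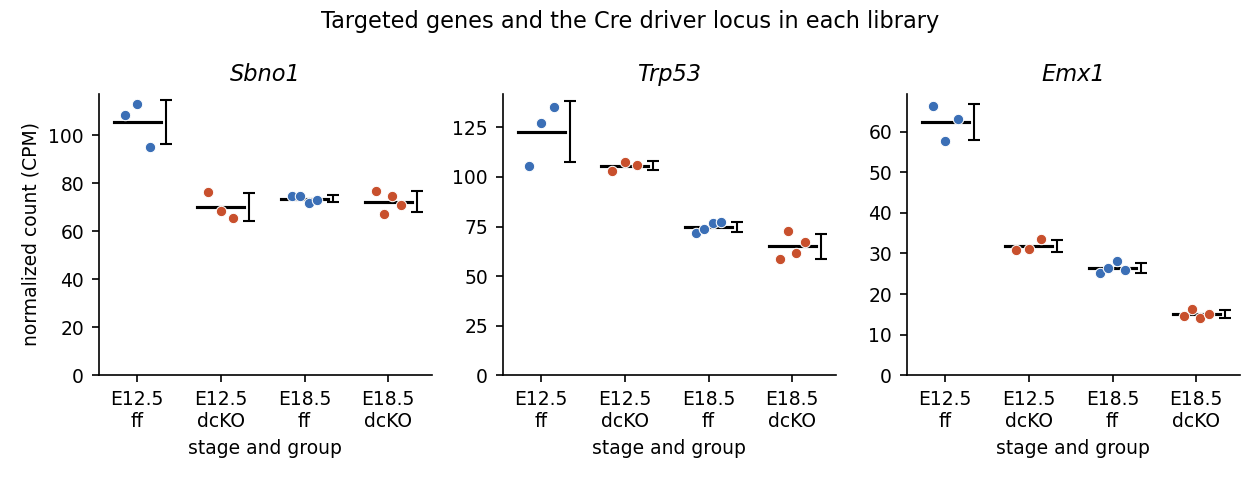
Normalized counts (CPM, vertical axis from 0) of Sbno1, Trp53 and Emx1 in each of the 14 libraries, by stage and group; points are libraries, horizontal lines are group means and bars to the right are ± 1 SD. Emx1 separates ff from dcKO at both stages, at 62.3 against 31.9 CPM and 26.4 against 15.1 CPM, while Sbno1 does so at E12.5 (106 against 70.2 CPM) but not at E18.5 (73.6 against 72.4 CPM).

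The E12.5 comparison asked which genes differ early in cortical development when both genes are targeted and the driver is present. Nfib and Nfix, members of the nuclear factor I family, fell from 311 ± 42.9 to 156 ± 19.4 CPM and from 201 ± 26.9 to 107 ± 14.7 CPM (SD, n = 3 each; log2 fold changes -1.0, SE 0.12, and -0.90, SE 0.12). Eomes, a marker of intermediate progenitors, fell by 0.74 on the log2 scale (SE 0.07). Tbr1 and Fezf2, regulators of deep-layer neurons, fell by 0.79 (SE 0.11) and 0.57 (SE 0.07). The proliferation marker Mki67 fell by 0.68 (SE 0.10). Other genes among the most lowered were Slc30a10, a manganese transporter (log2 fold change -1.33), Ttc39b (-1.20), and the driver locus Emx1 (-0.96). Cav1, the caveolar coat protein (-0.94), Timeless, a replication fork protein (-0.89), and Siah3 (-0.89) fell as well. The 5 named genes that rose were Nptx2, a neuronal pentraxin (0.86), the zinc finger gene Zfp580 (0.59), Uros, an enzyme of heme synthesis (0.59), the small GTPase Rac3 (0.55) and the mitochondrial thymidine kinase Tk2 (0.46), with SE of 0.07 to 0.12.

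**Figure D2:**
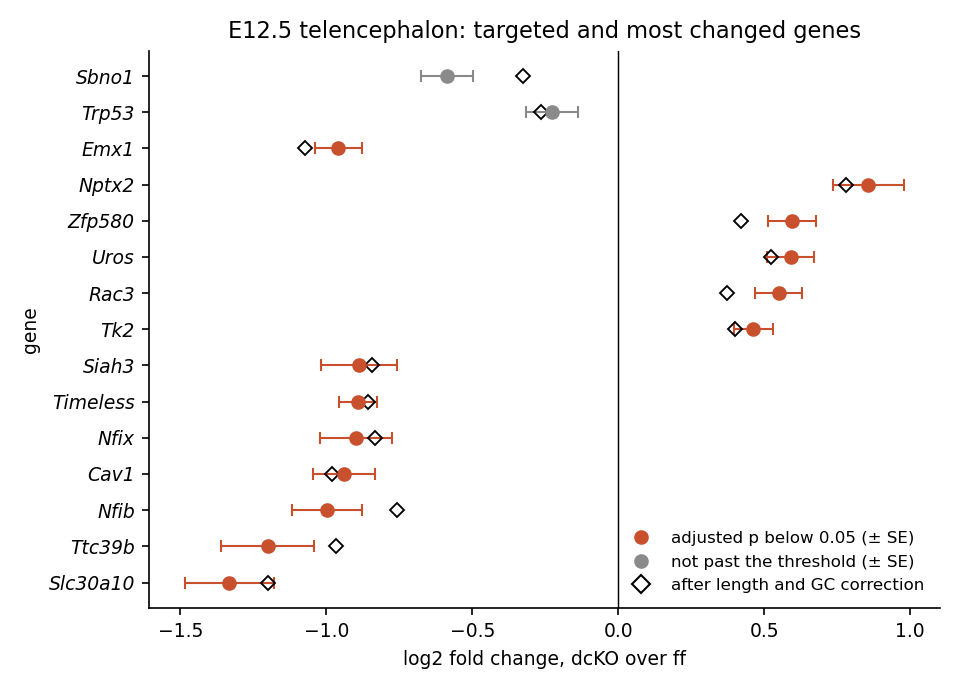
Log2 fold change of dcKO over ff at E12.5 (horizontal axis) for the targeted genes, the driver locus and the most changed genes (vertical axis), with 3 libraries per group; filled points with bars are edgeR estimates ± SE, coloured where the adjusted p was below 0.05, and open diamonds are the estimates after a correction for transcript length and GC content. Nfib moves from -1.0 to -0.76 with the correction and Timeless from -0.89 to -0.86.

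By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 34 of 17853 genes passed at E12.5, 7 higher and 27 lower in dcKO. All 34 had non-overlapping groups, as 10% of unselected genes would by chance, but calls are picked for a difference in the same libraries. Over all genes, 3433 genes had an unadjusted p under 0.05. The adjusted p of the named genes ran from 0.0064 (Timeless) to 0.048 (Rac3, Siah3 and Mki67). The E12.5 calls depended on single libraries. Without dcKO replicate 2 or 3, edgeR called 0 genes, with 1790 and 1723 at unadjusted p under 0.05, while DESeq2 called 267 and 317 and limma-voom 0. Without dcKO replicate 1 edgeR called 571, without ff replicate 3 it called 6, and without ff replicate 1 or 2 it called 71 and 77. With sex as a covariate 2 of the 34 calls were kept, and in male libraries alone 5 were. The fold changes of the genes called stayed about as large when these libraries were left out. Medians of the 27 lower and 7 higher genes were -0.75 and 0.59 without dcKO replicate 2, -0.74 and 0.58 without dcKO replicate 3, and -0.83 and 0.63 in male libraries. Fold changes at E12.5 also fell with transcript length (Spearman rho across genes -0.51). By library, the correlation of length with the deviation from the mean of the 6 libraries was -0.52 and -0.59 in dcKO replicates 2 and 3, 0.05 in dcKO replicate 1 and 0.06 to 0.55 in ff. Replicates 2 and 3 were also the closest pair, with a chi-square over degrees of freedom of 4.0 against 16.6 or more in the other 17 pairs of replicates. After a correction for length and GC content 26 of the 34 calls were kept. Among named genes it ended the calls of Nptx2 (log2 fold change 0.78, adjusted p = 0.052 in edgeR), Rac3 (0.37, adjusted p = 0.063), Nfix (-0.83, adjusted p = 0.051) and Tbr1 (-0.78, adjusted p = 0.052).

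The gene lists fixed beforehand gave less at E12.5. Among 18 intermediate progenitor markers only Eomes passed over all genes tested, and 6 were lower when adjusted over the list alone. Sstr2 (log2 fold change -0.63), Rhbdl3 (-0.48) and Neurod1 (-0.34) did not pass over all genes. The camera test with the preset correlation called this list lower (median log2 fold change -0.22, adjusted p = 0.0034), but with an estimated correlation its adjusted p = 0.44. Its estimated correlation was -0.0005, below the preset 0.01, yet its unadjusted p in camera rose from 0.0004 to 0.019. A call lost with an estimated correlation therefore need not come from correlated genes. In fry the list was lower (adjusted p = 0.015). Cell cycle genes showed 1 of 40 lower, Mki67, and 17 lower when adjusted over the list alone (median -0.26; camera adjusted p = 5.5e-11, but adjusted p = 0.62 with an estimated correlation). Deep-layer and subplate markers held 2 of 28 lower, Fezf2 and Tbr1, and 5 lower with 1 higher when adjusted over the list alone, with a list adjusted p of 0.48 in camera; their median of -0.01 and mean of 0.02 differed in sign. Camera also called 25 cholesterol biosynthesis genes lower (median -0.13, 2 lower when adjusted over the list alone, adjusted p = 0.0036), with adjusted p = 0.62 with an estimated correlation. It called 39 axon guidance genes lower (median -0.16, 4 lower when adjusted over the list alone, adjusted p = 0.00049) and the list of 6 targeted genes, paralogs and driver locus lower (median -0.23, 2 lower when adjusted over the list alone, adjusted p = 0.0097). With an estimated correlation these last lists had adjusted p = 0.75 and 0.44. Choroid plexus markers were called higher (16 tested, median 0.46, camera adjusted p = 0.00016, adjusted p = 0.44 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. Camera also called higher 21 thalamus and hypothalamus markers (0.35, 2 higher when adjusted over the list alone, adjusted p = 0.0061) and 35 ventral telencephalon and interneuron markers (0.04, 0 when adjusted over the list alone, adjusted p = 0.0097), both with adjusted p = 0.62 with an estimated correlation. The 13 mitochondrially encoded genes were called higher too (0.25, 0 when adjusted over the list alone, adjusted p = 0.0036, adjusted p = 0.62 with an estimated correlation). No member of these last 4 lists passed over all genes. The axon guidance, mitochondrial and ventral lists were no longer called after the length and GC correction (camera adjusted p = 0.22, 0.19 and 0.30), and without ff replicate 3, the female library, the cholesterol (0.070), ventral (0.070) and thalamus and hypothalamus (0.11) lists were not called. Without ff replicate 2 the axon guidance (camera adjusted p = 0.10) and ventral (0.073) lists were lost, and without dcKO replicate 1 the cholesterol (0.055) and ventral (0.11) lists. Camera with the preset correlation thus called 9 of 34 lists (4 higher, 5 lower) and 0 with an estimated correlation (3 at unadjusted p under 0.05), while fry called 4 in one direction and 19 in either. Of the 9 lists, fry in one direction kept 3: intermediate progenitor, choroid plexus (adjusted p = 0.047) and targeted genes (0.015). It lost 6: cell cycle (0.23), axon guidance (0.44), ventral (0.31), cholesterol, thalamus and hypothalamus, and mitochondrial (0.19 each). It also called Notch pathway genes lower (0.047).

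The E18.5 comparison asked how the cerebral cortex differs near birth. Most apical progenitor markers, cell cycle genes and ventral telencephalon and interneuron markers were higher in the libraries labelled dcKO, while most pan-neuronal, upper-layer and deep-layer markers and all cholesterol biosynthesis genes were lower. Camera called these lists with the preset correlation but not with an estimated correlation (adjusted p = 0.052 to 0.39). In one direction fry called each of them (adjusted p = 1.5e-05 to 0.0046). Crym, a deep-layer marker, fell from 62.4 to 22.6 CPM (log2 fold change -1.44, SE 0.10), and the upper-layer marker Dok5 had a log2 fold change of -1.71 (SE 0.10). Pax6, a transcription factor of radial glia, rose from 24.7 to 47.6 CPM (0.95, SE 0.07), and Slc32a1, the vesicular transporter of inhibitory neurons, from 55.2 to 102 CPM (0.89, SE 0.05; n = 4 per group throughout). By edgeR's test 5779 of 17974 genes passed, 2801 higher and 2978 lower, of which 1512 changed by at least 1.5-fold (1074 higher, 438 lower). The groups did not overlap for 5006 of the 5779, as 2.86% of unselected genes would not by chance, but the calls were picked for a difference in the same libraries. The median absolute log2 fold change of the calls was 0.38.

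The most raised named genes at E18.5 were expressed at low levels in ff. They included the histone gene H3c3 (log2 fold change 3.46, SE 0.46) and the interferon-inducible genes Ifit3b (3.26, SE 0.97), Ifi44 (2.46, SE 0.56) and Gvin2 (2.28, SE 0.47). BC049715 (2.99, SE 0.34), the vesicular monoamine transporter Slc18a1 (2.62, SE 0.43), AI849053 (2.26, SE 0.72) and Itprid1 (2.14, SE 0.19) rose as well. Ifit3b was at 5.70 CPM in replicate 2 labelled dcKO and at 0.38 to 0.74 CPM in the other 3. Without replicate 2 its log2 fold change was 1.47, that of Ifi44 was 1.6 and that of Gvin2 was 1.66, all still past the threshold in edgeR. With any 1 of the 4 ff libraries left out Ifit3b no longer passed, with a highest adjusted p of 0.11. AI849053 (adjusted p = 0.0498 in edgeR) was at 13 CPM in the shallow replicate 1 labelled dcKO and at 1.83 to 2.09 CPM in the other 3. Without replicate 1 its log2 fold change was 1.2, still past the threshold in edgeR. With any 1 of the 4 ff libraries left out it did not pass, with a highest adjusted p of 0.12. The most lowered were Dsc3, a desmosomal cadherin (-3.54, SE 0.27), Tac2, a tachykinin precursor (-2.68, SE 0.25), Glt28d2 (-2.65, SE 0.34) and the tight junction gene Cldn3 (-2.33, SE 0.47). They were followed by the homeobox gene Msx3 (-2.29, SE 0.27), Mlip (-2.28, SE 0.16), Usp43, a deubiquitinase family member (-2.22, SE 0.14), and the small heat shock gene Hspb3 (-2.19, SE 0.26). Apart from Ifit3b and AI849053, all of these stayed past the threshold in the 8 fits with 1 library left out. In male libraries Ifi44 (adjusted p = 0.099 in edgeR), Ifit3b (0.22) and AI849053 (0.25) did not pass. Their log2 fold changes there, 2.56, 3.36 and 2.20, were about as large as in all libraries. H3c3, Ifit3b, Gvin2 and Glt28d2 have close relatives or copies that could share reads. GENCODE M21 places exons of other genes over exons of BC049715, AI849053, Cldn3, Usp43, Gvin2 and Glt28d2, so the values of these genes are uncertain. The same holds for exons of Sbno1, Nfix, Slc30a10, Timeless, Eomes, Gli3, Fdft1 and Fabp3.

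Apical progenitor markers held 18 of 27 higher and 1 lower (Hopx, -0.30) at E18.5, and 19 higher and 1 lower when adjusted over the list alone (median 0.49; camera adjusted p = 3.8e-09, adjusted p = 0.12 with an estimated correlation). Nr2e1 (log2 fold change 1.03), Pax6 (0.95), Notch1 (0.89) and Sox9 (0.86), transcription factors and a receptor of radial glia, were its members with the lowest p. Of 40 cell cycle genes 31 rose and 0 fell, and 32 when adjusted over the list alone (median 0.46; camera adjusted p = 8.7e-12, adjusted p = 0.39 with an estimated correlation), among them Dtl (0.88), Hells (0.73), Mcm3 (0.53) and Mcm4 (0.44). Notch pathway genes went both ways, with 12 of 25 higher and 4 lower, or 12 and 5 when adjusted over the list alone (median 0.23, camera adjusted p = 0.014, adjusted p = 0.39 with an estimated correlation). Notch2 rose (0.65), while Dtx4, a Deltex family member, fell (-1.15). Of 35 ventral telencephalon and interneuron markers 28 rose and 2 fell (Olig2, -0.32, and Npy, -0.33), or 29 and 2 when adjusted over the list alone. Rarb (0.88) and Gad2 (0.83) rose beside Slc32a1, with a list median of 0.78 (camera adjusted p = 2.1e-14, adjusted p = 0.052 with an estimated correlation). Cajal-Retzius markers held 9 of 15 higher and 1 lower, or 9 and 2 when adjusted over the list alone (median 0.39; camera adjusted p = 0.00026, adjusted p = 0.34 with an estimated correlation). They include Cacna2d2 (0.60), the secreted signal Reln (0.58), Lhx1 (1.25) and Ebf3 (1.02).

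**Figure D3:**
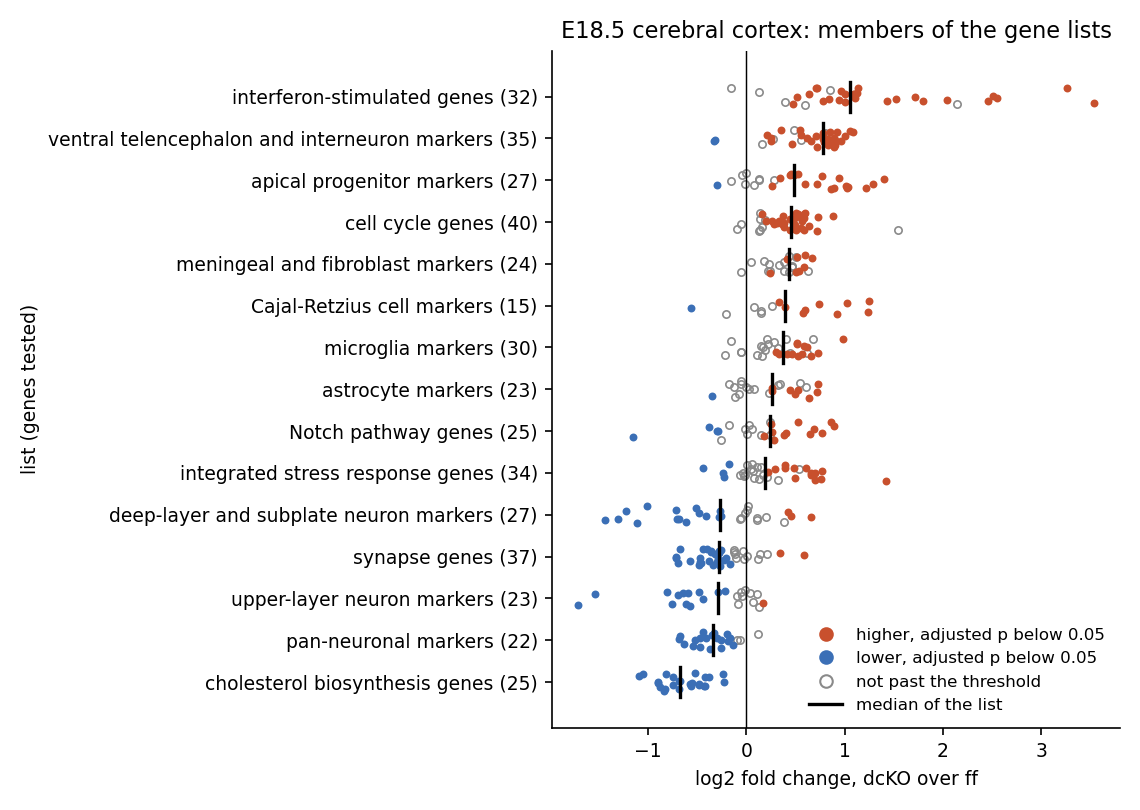
Log2 fold change at E18.5 (horizontal axis, libraries labelled dcKO over ff, 4 libraries per group) of each tested member of 15 gene lists that camera called with the preset correlation (vertical axis, number tested in brackets); points are genes, filled where the adjusted p was below 0.05, and black ticks are list medians. Medians run from 1.05 for interferon-stimulated genes to -0.68 for cholesterol biosynthesis genes; with an estimated correlation no list was called.

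All 25 cholesterol biosynthesis genes fell at E18.5, also when adjusted over the list alone, with a median of -0.68 (camera adjusted p = 1.4e-20, adjusted p = 0.10 with an estimated correlation). They include the squalene synthase Fdft1 (-0.90), Sqle, the squalene epoxidase (-0.83), Msmo1 (-0.82) and the mevalonate pathway enzyme Mvd (-1.05). Pan-neuronal markers held 19 of 22 lower and 0 higher, the same when adjusted over the list alone (median -0.34, camera adjusted p = 6e-10, adjusted p = 0.11 with an estimated correlation), such as Stmn2 (-0.68), Stmn1 (-0.69), the neuronal tubulin Tubb3 (-0.63) and the microtubule-associated Mapt (-0.54). Upper-layer markers held 13 of 23 lower and 1 higher, also when adjusted over the list alone (median -0.29; camera adjusted p = 1.2e-05, adjusted p = 0.22 with an estimated correlation), with Mef2c (-0.81) and Pou3f2 (-0.69) beside Dok5. Deep-layer and subplate markers held 15 of 27 lower and 3 higher, or 15 and 5 when adjusted over the list alone (median -0.27; camera adjusted p = 0.0002, adjusted p = 0.22 with an estimated correlation), with Nfe2l3 (-1.31), Ntsr1 (-1.01) and Ldb2 (-0.71) beside Crym. Synapse genes held 25 of 37 lower and 2 higher, or 25 and 4 when adjusted over the list alone (median -0.28; camera adjusted p = 2.8e-07, adjusted p = 0.44 with an estimated correlation), among them Camk2b (-0.69), Syt4 (-0.72), Scn2a (-0.68) and Nlgn1 (-0.72).

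Interferon-stimulated genes held 26 of 32 higher and 0 lower at E18.5, and 29 higher when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 7.7e-08, adjusted p = 0.47 with an estimated correlation). Xaf1 (1.80), Isg15, a ubiquitin-like modifier (1.72), the oligoadenylate synthetase relative Oasl2 (1.09) and Irf9 (0.48) rose. The list mean, relative to ff, was 0.50 to 1.85 on the log2 scale in the 4 libraries labelled dcKO, highest in replicate 2, and -0.24 to 0.21 in ff. Microglia markers rose beside them in 13 of 30 members, 14 when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 3.2e-05, adjusted p = 0.39 with an estimated correlation), such as C1qb (0.73), Csf1r (0.52) and C1qc (0.58). Sall1 (0.65), on the list, is also expressed by neural progenitors. Meningeal and fibroblast markers held 8 of 24 higher, 10 when adjusted over the list alone (median 0.43; camera adjusted p = 4.9e-05, adjusted p = 0.58 with an estimated correlation), for example Ogn (0.59) and Prrx1 (0.51). In one direction fry did not call this list (adjusted p = 0.066). Integrated stress response genes held 14 of 34 higher and 4 lower, or 15 and 4 when adjusted over the list alone (median 0.19; camera adjusted p = 0.0019, adjusted p = 0.34 with an estimated correlation). Psat1 (0.60), Sesn2 (0.77) and Shmt2 (0.39) rose and Xbp1 fell (-0.44). Astrocyte markers held 8 of 23 higher and 1 lower, the same when adjusted over the list alone (median 0.26, camera adjusted p = 0.028, adjusted p = 0.44 with an estimated correlation), with Sox21 (0.72), Apoe (0.63) and Fgfr3 (0.72) among them. The list was not called after the length and GC correction (adjusted p = 0.061), in male libraries (0.28), without ff replicate 2 (0.11) or without replicate 4 labelled dcKO (0.057). Camera also called the 4 tested chromosome Y and X-inactivation genes higher (median 1.40, no member past the threshold, adjusted p = 0.034, adjusted p = 0.56 with an estimated correlation), beside the uneven sexes of the groups. This call was lost after the length and GC correction (adjusted p = 0.15), without ff replicate 2 (0.12) or 4 (0.078) and without replicate 2 (0.081), 3 (0.071) or 4 (0.067) labelled dcKO.

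**Figure D4:**
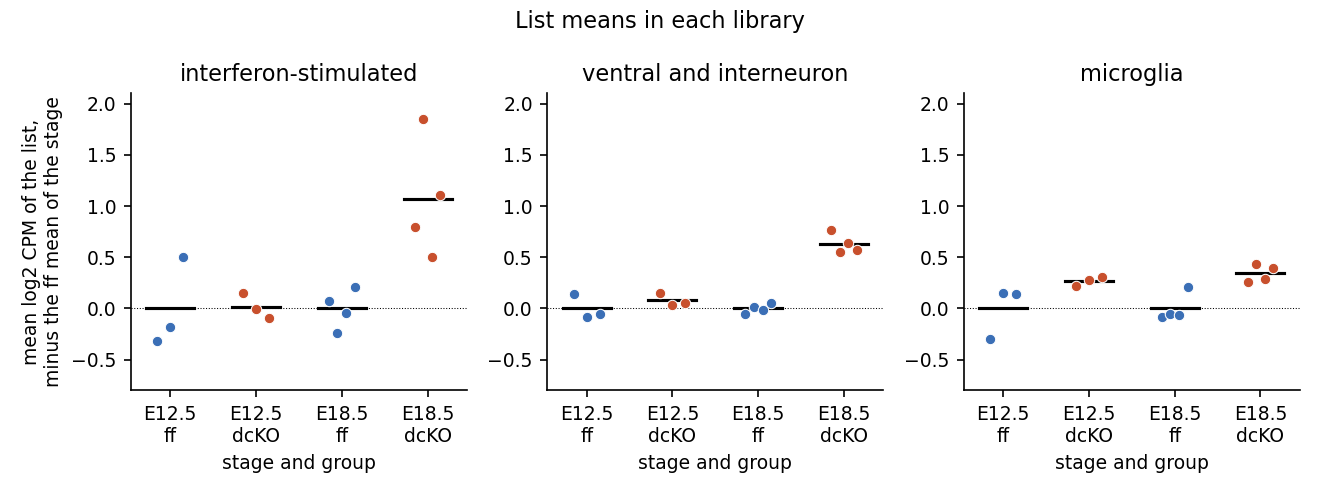
Mean log2 CPM of the interferon-stimulated, ventral telencephalon and interneuron, and microglia lists in each library, minus the ff mean of its stage (vertical axis), by stage and group; points are libraries and lines are group means. At E18.5 the interferon-stimulated mean spans 0.50 to 1.85 in the 4 libraries labelled dcKO, and the ventral mean spans 0.56 to 0.77.

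Camera with the preset correlation called 16 of 34 lists at E18.5 (11 higher, 5 lower) and 0 with an estimated correlation (6 at unadjusted p under 0.05), while fry called 17 in one direction and 29 in either. Of the 16 lists, fry in one direction kept 14 and called 3 others. It lost the meningeal and the chromosome Y and X-inactivation lists (adjusted p = 0.066 each). The p53 target genes were not called by camera, with an adjusted p of 0.46. Of 44 members 6 rose and 12 fell in edgeR, or 6 and 13 when adjusted over the list alone. Their median of 0.01 differed in sign from the test, which pointed to lower values. Crip2 (-0.78), the nuclease gene Aen (-0.50) and Bbc3, an apoptosis gene (-0.73), fell, while Sesn2 rose (0.77). The fry test of limma, which asks whether the genes move on balance one way, gave an adjusted p = 0.0095 toward lower values. At E12.5, 0 of 43 p53 target genes passed over all genes by edgeR, and 1 was higher and 5 lower when adjusted over the list alone (median -0.04, camera adjusted p = 0.20). At E18.5 the apoptosis genes had 6 of 27 higher and 7 lower, the same when adjusted over the list alone and with a median of 0.08 against a test toward lower values, with Bid (-0.46) and Casp9 (-0.35) lower. Intermediate progenitor markers had 6 of 19 higher and 6 lower, with Gadd45g higher (1.13) and Neurod1 (-0.87), Kif26b (-0.69) and Tac2 lower. Axon guidance genes had 10 of 39 higher, among them the guidance ligand gene Ntn1 (0.94), and 11 lower, among them Sema3c (-1.36), Nrp1 (-0.72) and Efna3 (-0.71). Immediate-early genes had 10 of 27 higher, such as Jun (0.59) and Ccn1 (0.79), and 4 lower, such as Nr4a3 (-1.23). Adjusted over the list alone, the counts were 7 and 8, 10 and 12, and 11 and 4 for the last 3 lists. In order, the camera adjusted p of these 4 lists was 0.75, 0.65, 0.46 and 0.071.

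The difference between the stages was tested with a genotype by stage interaction in all 14 libraries, in which stage and dissected region change together. Among the genes with more positive effects at E18.5 were Nr2e1 (log2 fold change -0.20 at E12.5 and 0.98 at E18.5, difference 1.19, SE 0.08) and Gli3 (-0.41 and 1.14, difference 1.55, SE 0.14). Others were Sox9 (difference 1.01, SE 0.09), Eomes (-0.74 and 0.28, difference 1.02, SE 0.09) and Dusp16, a phosphatase gene (difference 1.03, SE 0.09). The more negative effects at E18.5 were in Stmn2 (0.28 and -0.72, difference -1.0, SE 0.10) and Stmn4 (difference -0.90, SE 0.09), neuronal regulators of microtubules. They were also in Fdft1 (difference -0.88, SE 0.08) and Mvd (0.05 and -1.09, difference -1.14, SE 0.11), and in the fatty acid-binding protein gene Fabp3 (0.62 and -0.80, difference -1.42, SE 0.13). Their adjusted p ran from 3.9e-06 to 4.7e-05 in edgeR. The interaction passed for 3195 of 19327 genes, 1376 with the more positive and 1819 with the more negative effect at E18.5. It passed for 1733 and 1690 genes without E12.5 dcKO replicate 2 or 3. Among 40 cell cycle genes 28 had a more positive effect and 0 a more negative one, or 33 and 0 when adjusted over the list alone. Among 25 cholesterol genes 0 had a more positive and 19 a more negative effect, or 23 when adjusted over the list alone. With the preset correlation camera called 12 of 34 lists (7 up, 5 down), and 0 with an estimated correlation (5 at unadjusted p under 0.05; lowest adjusted p = 0.11).

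Across 17109 genes tested at both stages, the E12.5 and E18.5 effects had a Pearson r of -0.19 and a Spearman rho of 0.03; these are correlations across genes, which are not independent replicates. Of the E12.5 calls, 11 were lower at both stages, where 4.47 would be shared by chance (p = 0.0023, Fisher's exact test), and 3 were higher at both, against 1.11 by chance (p = 0.085, Fisher's exact test). The driver locus Emx1, Nfix (-0.90 and -0.91), Nfib (-1.0 and -0.46), Tbr1 (-0.79 and -0.51) and Fezf2 (-0.57 and -0.41) were lower at both. Nfia (-0.63 and -0.39), of the same family as Nfib, was lower as well and was picked here after its values were seen. Another 8 genes changed in opposite directions, among them Eomes (-0.74 and 0.32), Mki67 (-0.68 and 0.63) and Sall1 (-0.72 and 0.65). With DESeq2's calls, 233 genes were lower at both stages, where 239 would be by chance, and 55 were higher, where 49.6 would be, so the excess of shared calls did not hold with those calls. After the length and GC correction 48 were lower, against 22.6 by chance, and 11 higher, against 4.61. With a mean of at least 1 CPM 11 were lower, against 5.2, and 3 higher, against 1.15.

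The deposited DESeq2 tables, made by the submitters, called 1247 genes at E12.5 (325 higher, 922 lower) and 6315 at E18.5 (2842 higher, 3473 lower). They shared 32 of the 34 and 5547 of the 5779 edgeR calls, all with the same sign. A DESeq2 run on the same rounded counts called 1247 genes at E12.5, all shared with the deposited table. Between ff at E12.5 and ff at E18.5, where stage and region differ together, 11862 genes passed in edgeR (6085 higher and 5777 lower at E18.5). All 40 cell cycle genes and 21 of 27 apical progenitor markers were lower at E18.5 (medians -2.44 and -1.83), 36 of 37 synapse genes and 19 of 23 astrocyte markers were higher (medians 1.72 and 1.84), and 21 of 22 thalamus and hypothalamus markers were lower (median -4.59).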

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

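All tests in this part that weigh an explanation, the length and GC correction included, were chosen after the results were seen, except the splits of the samples other than the relabelings of the E12.5 libraries alone in the interaction, and except the fits with 1 library left out, which were planned but whose bounds were set later.

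The first pattern is the 27 genes lower in dcKO at E12.5, with a median log2 fold change of -0.79. Which genes passed depended on single libraries. edgeR called 6 genes without ff replicate 3, the female library, and 0 without dcKO replicate 2 or 3 (1790 and 1723 at unadjusted p under 0.05, DESeq2 267 and 317, limma-voom 0). The median of the 27 genes was -0.83 without ff replicate 3 and -0.75 and -0.74 without dcKO replicate 2 or 3. Neither the size nor the direction of these medians is an independent test, as the genes were called on the same libraries and all have separate groups. Whether the female library, or either dcKO library alone, added to the fold changes is therefore not decided. A trend with transcript length and GC content did not account for all of it, since of the 26 with an annotated length, all 26 stayed lower after the correction, 22 past the threshold, with a median of -0.70 (quartiles -0.84 and -0.51). More tissue from outside the dorsal telencephalon stays open: 73 progenitor and deep-layer markers had a median of -0.12, but they include Nes, Fabp7 and Notch1, which other progenitors express too, while Eomes (-0.74), Tbr1 (-0.79) and Fezf2 (-0.57) fell, and choroid plexus (median 0.46) and thalamus and hypothalamus markers (0.35) had higher means in all 3 dcKO libraries than in every ff library. Such tissue and an effect of the knockout cannot be told apart, because the labels do not describe the borders of the dissection, and a difference shared by dcKO replicates 2 and 3, the closest pair of replicates, was not tested beyond length and GC content.

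The second pattern is the rise of interferon-stimulated genes in the libraries labelled dcKO at E18.5, with a median of 1.05. More microglia would need microglia markers to rise as much, but their upper quartile was 0.56 and 0 of 30 reached 1.05. Female libraries among ff did not account for it, since the median was 1.01 in male libraries (lower quartile 0.77, 9 of 34 genes past the threshold, camera adjusted p = 1.7e-06). Nor did replicate 2 alone, as the median without it was 0.82, with 22 of 32 genes past the threshold (camera adjusted p = 1.7e-07), although with an estimated correlation camera did not call the list in all libraries (adjusted p = 0.47). Camera with the preset correlation called at least 16 lists in 14 of 35 splits of the E18.5 libraries. Its p-values therefore carry little weight, and both points rest on the medians. An interferon response in these embryos may be a candidate explanation, while a difference between litters or in infection state was not tested and stays open.

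The third pattern is the rise of ventral telencephalon and interneuron markers beside lower excitatory neuron markers at E18.5. A lower share of excitatory neurons that raised every other cell type alike would lift their markers together, but the ventral median was 0.78 and the endothelial upper quartile was 0.21. Medians were 0.26 for astrocyte and 0.24 for oligodendrocyte lineage markers. They were 0.37 for microglia, 0.43 for meningeal and 0.39 for Cajal-Retzius markers. A lower share with unequal rises of the other cell types was not tested and stays open. Striatal tissue in the dissections stays open: striatal markers, of which 8 of 14 are also on the ventral list, had a median of 0.85 (quartiles 0.24 and 0.89), against 0.46 for cortical interneuron markers. Drd1 (0.16), Ppp1r1b (0.14) and Pde10a (0.15) did not pass the threshold while Drd2 (0.83) did, so striatal markers did not move alike. A change of cell fate, a lower share of excitatory neurons and striatal tissue therefore cannot be told apart, because the labels do not describe the borders of the dissection and cell shares were not measured.

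Other splits of the libraries gave the following. At E12.5 the real split gave 34 genes and the highest other split 1 (1 of 10 splits), but 10 splits are too few for a share under 0.05. At E18.5, the real split gave 5779 genes and the highest other split 1, so chance was excluded (1 of 35 splits). For lists at E18.5 chance was not excluded, since 14 of 35 splits called at least 16 lists, the highest 22. At E12.5, 8 of 10 splits called at least 9 lists, the highest 13, and 10 splits are too few for a share under 0.05. In the interaction, 1 of 50 splits of both stages drawn gave as many as 3195 genes, and the highest other, 1996, kept the real E18.5 split, so chance was excluded only for both stages at once. With the real E18.5 groups kept, 2 of 20 relabelings of the E12.5 libraries gave as many, the real one and its reverse (3284), and 20 are too few for a share under 0.05. For its lists chance was not excluded, since 22 of 50 splits called at least 12, the highest 21. For stage in ff the real split gave 11862 genes and the highest other 6726, so chance was excluded (1 of 35 splits).

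In 8 of 108 groups of 4 libraries tested, 1 library lay far from the other 3, where chance gives about 1 in 20. The ff replicate 4 of E18.5 had a mean log2 CPM of 8.86 for pan-neuronal markers (others 8.94), 2.70 for microglia markers (2.41 to 2.44) and 4.36 for erythroid genes (3.34 to 3.42). The dcKO replicate 1 of E18.5 had a total of 5.98 M counts (others 48.6 to 53.9 M) and a mean of 3.46 for the targeted genes and paralogs (4.17 to 4.20). The dcKO replicate 3 of E18.5 had a choroid plexus mean of 0.46 (3.54 to 3.92). Ifit3b was at 5.70 CPM in dcKO replicate 2 and AI849053 at 13 CPM in dcKO replicate 1.

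The effect of dcKO differed between the stages, by the interaction test, for 3195 genes. Differences were 1.19 for Nr2e1, 1.03 for Dusp16, 1.55 for Gli3, 1.02 for Eomes and 1.01 for Sox9. They were -1.42 for Fabp3, -0.88 for Fdft1, -0.90 for Stmn4, -1.14 for Mvd and -1.0 for Stmn2. List medians were 0.50 for apical progenitor markers, 0.62 for ventral markers, 0.65 for cell cycle genes, 0.28 for Notch pathway genes and 1.15 for interferon-stimulated genes, the last with 13 of 34 members past the threshold. Those of microglia markers (0.11) and meningeal markers (0.24) were smaller. Medians were -0.15 for deep-layer, -0.30 for upper-layer, -0.26 for pan-neuronal markers, -0.23 for synapse genes and -0.56 for cholesterol genes. All 12 lists were called by camera with the preset correlation; with an estimated correlation their adjusted p was 0.11 to 0.81.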

How the results depend on the processing

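The alternatives with the length and GC correction, male libraries, thinned counts, a reduced E18.5 dcKO group, both shallow libraries left out, and those for stage in ff were chosen after the results were seen. The count of 34 genes at E12.5 varied most: 56 with DESeq2 size factors, 1247 with the DESeq2 Wald test, 124 with limma-voom, 244 with no filter, 9 with a mean of at least 1 CPM, 1079 in 1 fit of all 14 libraries, 3 with sex as a covariate, 56 without erythroid, chromosome Y, Xist and mitochondrial genes, 142 after the length and GC correction, 6 in male libraries and 112 with thinned counts. With 1 library left out it was 0 (without dcKO replicate 2 or 3, with 1790 and 1723 at unadjusted p under 0.05 in edgeR) to 571 (without dcKO replicate 1). Sbno1 at E12.5 passed the threshold with DESeq2 size factors (-0.59), the DESeq2 test (-0.59), limma-voom (-0.58), no filter (-0.59), 1 fit of all libraries (-0.58), erythroid and other genes removed (-0.59), the length and GC correction (-0.33), thinned counts (-0.61) and dcKO replicate 1 left out (-0.65), and was -0.66 to -0.53 with 1 library left out. Emx1 at E12.5 missed it with sex as a covariate (-0.94) and without dcKO replicate 2 (adjusted p = 0.11) or 3 (0.063) in edgeR, and was -1.01 to -0.92 with 1 library left out. The E18.5 count of 5779 was 1512 with a fold change of at least 1.5 and 3686 with thinned counts, 4417 to 5723 with 1 library left out. Trp53 at E18.5 missed the threshold with upper quartile scaling (-0.17), sex as a covariate (-0.18), male libraries (-0.21), thinned counts (-0.20), dcKO reduced to replicates 2 and 4 (-0.10) and TPM (-0.10), and was -0.26 to -0.16 with 1 library left out. Sbno1 at E18.5 was higher in TPM (0.34). Lists called at E12.5 were 0 with an estimated correlation (3 at unadjusted p under 0.05), 4 and 19 with fry in one or either direction, and 9 to 14 with 1 library left out. Those at E18.5 were 0 with an estimated correlation (6 at unadjusted p under 0.05), 29 with fry in either direction, and 14 to 19 with 1 library left out. The interaction gave 1690 to 3307 genes with 1 library left out. Shared calls, 14 in edgeR, were 288 with DESeq2 and 59 after the length and GC correction. The median of synapse genes at E12.5 was -0.18 to 0.056 with 1 library left out, highest without ff replicate 2, where camera called the list higher (adjusted p = 0.027). That of choroid plexus markers at E18.5 was -0.25 to 0.45, highest without dcKO replicate 3, and 0.38 with dcKO reduced to replicates 2 and 4. In these fits camera called the list higher (adjusted p = 0.020 and 0.037). The test toward lower values thus rested on replicate 3, whose list mean was 0.46 log2 CPM against 3.54 to 3.92 in the rest of its group. In the other cases the cause was not tested, beyond fewer libraries or counts where the alternative removes them. For named genes other than Sbno1, Trp53 and Emx1, 5128 comparisons with an alternative stayed on the same side of the threshold, 204 gained and 170 lost the call, and 0 reversed. A change of sign was counted as a reversal only where either fit passed the threshold. For lists, judged by the direction and adjusted p of the list test, the counts were 737, 51, 59 and 3. With counts thinned to the shallowest library, 32 of the 34 calls at E12.5 and 3444 of the 5779 at E18.5 were kept. No paired analysis was possible because the numbers in the column names are not shared between groups within a stage, and the library names in the descriptions, whose first numbers are, belong in 11 of 14 samples to columns of another group or stage.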

Other observations

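The striatal and interneuron markers, the mitochondrial transcript values and the transcript length values in this part were chosen after results were seen. At E18.5, striatal markers rose in 10 of 14 cases in the libraries labelled dcKO and fell in 0, among them the transcription factor genes Six3 (log2 fold change 1.09), Zfp503 (1.01) and Isl1 (0.96), the dopamine receptor gene Drd2 (0.83) and the enkephalin precursor Penk (0.80). Of 11 cortical interneuron markers 9 rose and 2 fell: Erbb4 (0.78), Maf (0.72), Lhx6 (0.55) and Sst (0.46) rose, and Satb1 (-0.59) and Npy (-0.33) fell.

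Other lists were not called by camera at E18.5. Wnt targets held 7 of 22 higher and 2 lower, with Ccnd2 higher (0.59) and Wnt7b lower (-0.71). Hypoxia and glycolysis genes held 6 of 32 higher and 5 lower, with Hk2 higher (0.83) and Ndrg1 lower (-0.63), and their median of -0.03 and mean of 0.04 differed in sign. Oligodendrocyte lineage markers held 4 of 15 higher and 3 lower, and reactive and phagocytic microglia genes held 6 of 26 higher and 3 lower, with Lpl lower (-1.0). Endothelial markers held 2 of 25 higher and 1 lower, pericyte and mural cell markers 2 of 17 higher, and erythroid genes 1 of 11 higher and 1 lower (median -0.78). Thalamus and hypothalamus markers held 4 of 14 higher and 0 lower, with Otx1 (0.61) and Tcf7l2 (0.75), and cortical hem and hippocampal markers 7 of 19 higher and 1 lower, Dkk3 (-0.79). Choroid plexus markers had 1 of 16 lower, Rspo2 (-0.92), with a median of 0.05 against a test toward lower values. Without dcKO replicate 3, camera called the list higher (median 0.45, adjusted p = 0.020). Mitochondrially encoded genes had 0 of 13 changed in edgeR (median 0.16). The targeted genes, paralogs and driver locus had 1 of 6 higher, Trp73 (0.39), and 2 lower, Emx1 (-0.81) and Trp53 (-0.20). Reference housekeeping genes held 2 of 14 higher and 3 lower, such as B2m (0.52), also an interferon-stimulated gene, and Ywhaz (-0.37). Adjusted over the list alone, higher and lower counts at E18.5 were 6 and 6 for hypoxia genes, 5 and 3 for oligodendrocyte lineage markers, 7 and 3 for reactive microglia genes, 1 and 1 for endothelial markers, 1 and 0 for pericyte markers and 2 and 2 for the targeted genes, and equal to those over all genes for the other lists of this paragraph.

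At E12.5, the lists not called by camera had median log2 fold changes of -0.11 for apical progenitor markers, -0.18 for upper-layer markers, 0.13 for Cajal-Retzius markers, 0.00 for pan-neuronal markers, -0.06 for synapse genes, 0.06 for astrocyte markers and 0.21 for oligodendrocyte lineage markers. They were 0.19 for microglia markers, 0.23 for reactive microglia genes, 0.07 for endothelial, -0.02 for pericyte and 0.10 for meningeal markers, 0.22 for erythroid genes and 0.17 for cortical hem markers. They were -0.04 for Notch pathway genes, 0.10 for Wnt targets, -0.02 for apoptosis, 0.04 for integrated stress response and 0.04 for immediate-early genes. Hypoxia genes had -0.04, interferon-stimulated genes -0.13, chromosome Y and X-inactivation genes 0.51 and housekeeping genes 0.02. Over all genes edgeR called 0 members of these lists apart from Sall1 among microglia markers. Adjusted over the list alone, 8 Notch pathway genes were lower, 3 astrocyte markers higher and 2 lower, 2 erythroid genes higher, and at most 1 gene per direction in any other. In one direction fry called the Notch pathway genes lower (adjusted p = 0.047), while camera did not (adjusted p = 0.067). The pan-neuronal mean of -0.03 differed in sign from a test toward higher values.

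Sbno1 differed between units. In TPM it was 26.3 ± 3.47 in ff and 15.2 ± 2.0 in dcKO at E12.5 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). At E18.5 it was 16.9 ± 1.55 in ff and 21.7 ± 3.27 in the libraries labelled dcKO (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). The transcript length implied by counts and TPM was 0.842 times that of ff at E18.5, a change as large as in 1.79% of 13151 genes, and 1.12 times at E12.5.

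The mitochondrial transcript mt-Nd6, which lies on the strand opposite most mitochondrial genes, was at 81.0 CPM in E12.5 ff replicate 1 and 1.84 to 4.93 CPM in the other E12.5 libraries. It was at 190 CPM in E18.5 dcKO replicate 1 and 2.78 to 7.61 CPM in the other E18.5 libraries. These are the 2 shallow libraries. AI849053, whose exons overlap a gene on the opposite strand, was at 27.9 CPM in the former. Another protocol or strand setting for these libraries was not tested, and the counting strand was not stated. Their counts for genes overlapped on the opposite strand, AI849053 at E18.5 included, are therefore uncertain. Hbb-bs was at 49.6 to 259 CPM in the libraries labelled dcKO at E18.5 and 333 to 600 CPM in ff. The chi-square over degrees of freedom between replicate pairs was 4.0 to 41.7 over 18 pairs.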
